A study of Drosophila melanogaster with 2 samples.

How the data were processed

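The series holds chromatin immunoprecipitation sequencing of Ftz-F1, an orphan nuclear receptor of the fly, from whole Drosophila melanogaster embryos of mixed sex collected over 0 to 24 hours. Per the labels, the flies carried a transgene that makes Ftz-F1 fused at its C-terminus to enhanced green fluorescent protein, and an antibody against that tag was used for the immunoprecipitation. Chromatin was sonicated, and the labels give a size range of 200 to 800 for both libraries. The 2 libraries are labelled biological replicates 1 and 4 of 1 group, with a separate biosample for each. Nothing in the labels says whether they came from separate fly cultures. P-values over peaks therefore describe these lists, and the spread between the replicates may be partly technical.

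The authors deposited peak lists in the genome builds dm6 and dm3. For each replicate, and for both replicates pooled, the deposited list is the input to an irreproducible discovery rate (IDR) analysis, which keeps peaks whose ranks repeat between replicates. Per the file listing deposited with the samples, those lists hold peaks together with background regions, and a control library entered the calls. Each input list has 30000 entries. The thresholded list, here called the IDR list, was made by the authors from the replicate lists and the pooled list. The aligner, the peak caller, the control's identity and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' own, on a scale that the deposited files do not state, and it was used only to rank, filter and describe peaks within 1 list or between lists as ranks. The column of −log10 q-values deposited by the authors reached a highest value of 4.18, which 7579 pooled peaks in dm6 shared, so it could not rank the stronger peaks. Read counts behind a peak are unknown, and so is sequencing depth. The confidence intervals on shares of peaks cover counting error only.

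All 3960 peaks of the dm6 IDR list were found in the pooled dm6 list, where they held ranks 1 to 3960 by signal value. The remaining 26039 pooled peaks on the chromosome arms are called sub-threshold peaks. Positions are 1-based dm6 coordinates. Chromosome sequence came from the release 6 reference assembly and gene models from Ensembl release 115 (BDGP6.54), which share the dm6 coordinates. No dm3 sequence or annotation was used, and nothing was converted between builds, so dm3 lists entered only counts, overlaps, the rank correlation and the X share. Arms 2L, 2R, 3L, 3R, 4 and X were analysed. Gene models with the transposable element type were left out. The summit is the position the deposited list gives inside each peak.

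Replicates were compared by the share of the strongest 3960 peaks of replicate 1 that overlapped, by at least 1 bp, one of the strongest 3960 of replicate 4. The comparison set was 1000 random placements of the replicate 4 peaks on the same arm, outside unknown bases (a permutation test of positions, one-sided). Each summit was put in 1 class in the order promoter (within 500 bp of any transcript start), 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic, and compared with 1000 random placements (the same test, two-sided) and with sub-threshold peaks (Fisher's exact test, two-sided). The Ftz-F1 site was written as the consensus YCAAGGYCR (Y is C or T, R is A or G) and sought on both strands within 100 bp of each summit. The control was a window of the same size 1000 bp to the right of the same summit, compared by the exact McNemar test (two-sided). A reversed consensus with the same letters, RCYGGAACY, served as a composition control, and 15 consensus sequences were tested as 1 family. Peaks per arm were set against arm length by an exact binomial test.

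A protein-coding gene was counted as holding a peak when an IDR summit lay in its body or up to 2000 bp upstream. Each of 15 gene lists was compared with 10000 random lists of protein-coding genes matched on the decile of gene length (a permutation test of list membership, two-sided). Families of tests were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and shares carry 95% Wilson intervals. The tests, the lists, the consensus sequences and the rule for named genes were fixed before the data were examined. The rule names the 20 IDR peaks with the highest signal value, up to 4 members of each list by the signal value of their strongest peak, and ftz-f1, ftz, Hr39 and en in any case. List symbols were matched to the annotation, 7 of them through a current name.

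Alternatives covered the overlap rule, the promoter and motif windows, the motif definition, the control window, sub-threshold peaks as background, the strongest 1980 IDR peaks, the dm3 lists, gene assignment, length matching, and each replicate left out. Leaving out a replicate meant taking the strongest 3960 peaks of the other one, since the IDR list needs both. One alternative, the strongest peak of each run of overlapping IDR peaks (3697 peaks), was chosen after seeing the data. The statistics were tested on simulated data. Of 100 sets of 3960 random summits, 7% gave a motif p under 0.05. Sites planted at 18.9% of 3960 random summits came back as an excess of 18.3%, and 60.3% planted shared peaks came back as 61.2%. Lists of 25 drawn from the 13945 genes by length, with no planted effect, passed the unadjusted threshold in 4.5% of cases with length matching and 66% without it. When members of such a list that lacked a peak were given one at a chance of 50%, 32.5% passed. In this simulation the chance of a peak rose with gene length by a rule not fitted to the data. The 66% and the 32.5% therefore need not hold for the real lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Signal tracks, alignments and the control library were not analysed here.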

Results

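Ftz-F1 binding was measured by chromatin immunoprecipitation sequencing in whole embryos aged 0 to 24 hours, with an antibody against the green fluorescent protein tag on Ftz-F1. Ftz-F1 is known as a partner of the homeodomain protein Fushi tarazu in embryonic segmentation and as a competence factor for the steroid hormone ecdysone. There was 1 group with 2 biological replicates, numbered 1 and 4, and no second condition, so the comparisons are between the replicates and between peaks and their genomic background. The authors' IDR list in dm6 held 3960 peaks, in 3697 regions after merging overlapping peaks. Of these peaks, 2680 had the same width of 444 bp, and widths ranged from 111 to 3775 bp. The authors' signal value had a median of 131 in the pooled data (quartiles 108 and 184) and ranged from 91.8 to 3557. Read depth is unknown from peak lists, so a gene without a peak is a gene without a listed peak.

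The first question was which genes carried the strongest Ftz-F1 signal. The ftz-f1 gene itself held 3 of the 20 strongest IDR peaks, and genes of the ecdysone pathway Hr39 and Eip75B held 1 each. The strongest summit of ftz-f1 (FBgn0001078, 3L, 18750607 to 18801309, minus strand) lay 155 bp upstream of the gene at 3L 18801464 in a promoter, with a signal value of 1929, or 14.7 times the list median. It ranked 5 in replicate 1 and 6 in replicate 4. Further ftz-f1 peaks with summits at 18759405 (signal value 1359) and 18771533 (905) lay in introns. Hr39, which encodes the nuclear receptor most closely related to Ftz-F1, had an intronic summit at 2L 21250964 with a signal value of 1060, ranked 14 and 17 in replicates 1 and 4. Eip75B, an early ecdysone response gene that encodes a heme-binding nuclear receptor, had an intronic summit at 3L 18029755 with a signal value of 931, ranked 12 and 43.

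The strongest peak of all, with a signal value of 3557 and rank 1 in both replicates, had its summit at 2L 2197111 in an intron of COX7AL2, a subunit-like gene of cytochrome c oxidase, and another peak (rank 11, 1160) lay between genes beside it at 2198885. The next ranks were an intron shared by CG6191 and CG45088 (2R 13584347, 2424), an intergenic peak 1675 bp from Rh5, a rhodopsin gene (2L 12006478, 2261), and a summit inside beat-Ib (2L 15911653, 2093) within 500 bp of a transcript start, whose nearest protein-coding start belonged to CG13244. An intron of the dynein heavy chain gene Dhc64C (3L 4824556, 2092) ranked 5. Promoter peaks of the glycolytic gene Pglym78 (3R 29148303, 1776), of Der-1, which acts in protein degradation at the endoplasmic reticulum (2L 1974090, 1290), of the nucleotide exchange factor gene Rcc1 (3L 5932632, 1030) and of the elongin gene EloB (3R 20579901, 945) were also among the 20. So were a promoter-class peak 2020 bp from CG10939 (2R 17392573, 1405), an intron of the reticulon gene Rtnl1 (2L 5001468, 1132), an intron of ush, a regulator of GATA factors (2L 481056, 1053, nearest start cbt), an intergenic peak near CG13321 (2R 12955983, 1008) and a summit shared by the bodies of kirre, a myoblast fusion gene, and CG32795 (X 2790317, 1005). For the Hr39 peak the nearest protein-coding start was that of l(2)k14505. In replicate 1 these 20 peaks ranked between 1 and 25, and in replicate 4 between 1 and 43.

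Among genes of the ecdysone response, 3 on 3L held many summits. Eip75B held 42 IDR summits, the highest number of any protein-coding gene, and ftz-f1 held 22, the next highest. Eip74EF, an ETS-family early ecdysone gene, held 15. The ecdysone receptor gene EcR on 2R held 9 and the nuclear receptor gene Hr4 on the X held 8, and other members of that list on 3L, such as Eip78C (2), Blimp-1 (1) and ImpE1 (0), held few or none. Outside that pathway rdx, which encodes a substrate adaptor for ubiquitin ligase, held 19, ush held 16 and tara held 14. Per 100 kb of gene and upstream sequence this came to 36.3 summits in Eip75B, 41.7 in ftz-f1 and 23.9 in Eip74EF, but 10.8 in EcR and 11.8 in Hr4. Outside the pathway it came to 38.2 in tara, 28.4 in rdx and 24.1 in ush. Genes with fewer summits could be as dense or denser, such as bbx (7 summits, 57.8 per 100 kb) and CG14434 (7, 40.5). Most of the Eip75B summits (35 of 42) lay more than 500 bp from a transcript start.

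**Figure D1:**
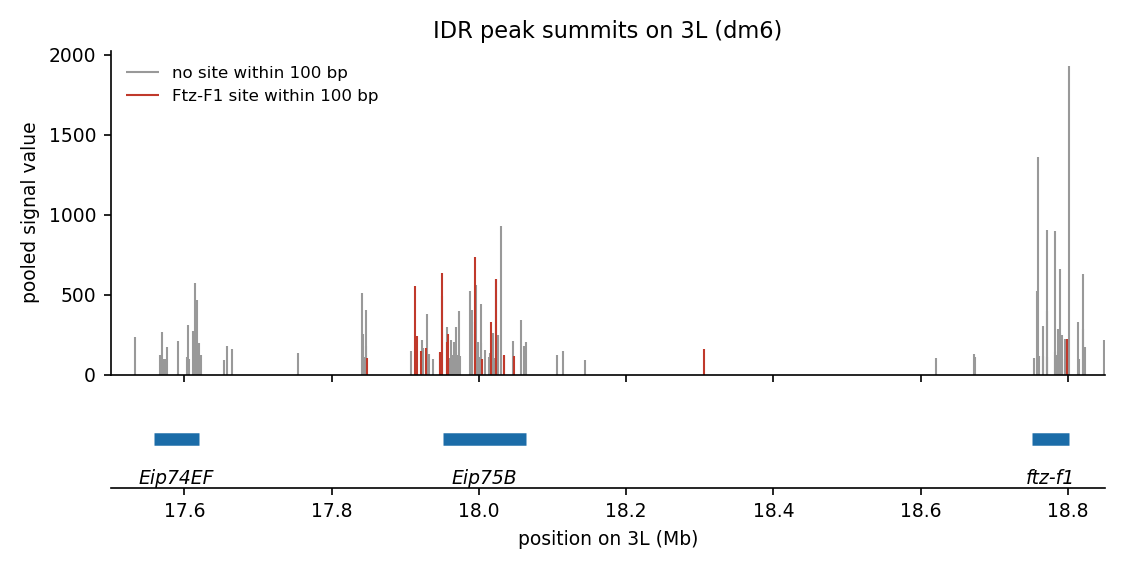
Map of IDR peak summits on 3L (dm6) around Eip74EF, Eip75B and ftz-f1. Each vertical line is 1 of 120 summits, its height the authors' pooled signal value, red where a Ftz-F1 site lies within 100 bp (17 summits); blue bars mark the 3 gene bodies, which hold 77 of the summits.

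The replicates shared most of their strong peaks. Of the strongest 3960 peaks of replicate 1, 2748 overlapped one of the strongest 3960 of replicate 4 (69.4%, 95% Wilson interval 67.9 to 70.8), against a mean of 2.41% in 1000 random placements (28.8-fold, one-sided permutation p = 0.000999 over positions, the smallest the placements can give). The share hardly changed with depth. It was 71.2% for the strongest 250 peaks and 71.5% at a depth of 30000, where background regions are included and random placements gave 17.8%. Stronger peaks thus agreed no better than the whole lists. Random placements ignore where peaks can be called, so the fold does not measure agreement in Ftz-F1 binding alone. In the IDR list, 3945 of 3960 peaks (99.6%) overlapped a peak in each replicate's full list, and 2760 (69.7%) overlapped the strongest 3960 of both. Across those peaks the signal values of the replicates had a Spearman rho of 0.536 (95% interval 0.514 to 0.558). Peaks are not independent replicates, and the range of signal within the IDR list is restricted by its threshold. The authors made the IDR list from these same replicate lists and the pooled list, keeping peaks whose ranks repeat. The 99.6% and 69.7% are therefore no separate evidence that the replicates agree.

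Ftz-F1 peaks lay mainly at promoters. Of the 3960 summits, 2415 (61.0%, 59.5 to 62.5) were within 500 bp of a transcript start, compared with 13.7% of random placements (4.46-fold, adjusted permutation p = 0.0028, from the smallest p the placements allow). Introns held 1091 summits (27.6% against 39.3% at random) and intergenic sequence held 302 (7.63% against 27.3%), and both were below random with the same adjusted p. Coding exons held 65 summits (1.64% against 13.7%) and 3' UTRs held 34 (0.859% against 4.36%), also below random. The share in 5' UTRs, 0.859%, did not pass the test against random placements (0.776% on average, two-sided permutation p = 0.615). Sub-threshold peaks were at promoters in 35.7% of cases, fewer than IDR peaks (odds ratio 2.81, adjusted p = 2.23e-196, Fisher's exact test).

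**Figure D2:**
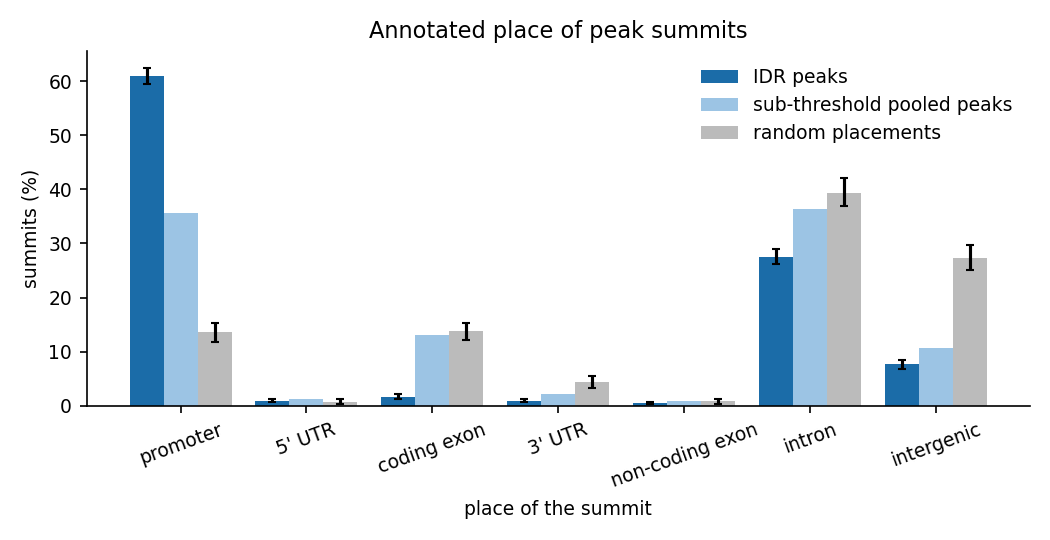
Percent of summits in each annotated class (y axis) for IDR peaks (dark blue, 95% Wilson intervals), sub-threshold pooled peaks (light blue) and random placements (grey, bars from the lowest to the highest of 1000 placements). Promoters hold 61.0% of IDR summits, 35.7% of sub-threshold summits and 13.7% of random positions.

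The Ftz-F1 site was enriched at summits but present in a minority of them. YCAAGGYCR lay within 100 bp of 259 of 3960 summits (6.54%, 5.81 to 7.35), against 1.44% of control windows, a 4.54-fold excess (two-sided exact McNemar p = 7.62e-33). The stricter CAAGGTCA was found at 4.02% of summits against 0.480% (8.37-fold; 5.34-fold with replicate 4 left out, and 4.42-fold with the control window 2000 bp away), and the looser AAGGYCR at 18.5% against 7.17% (2.57-fold). Among the 8 versions of the consensus, TCAAGGTCA was the most frequent, at 67 summits and 10.3 times its share in control windows. The median distance from site to summit was 31 bp. The reversed consensus was less frequent at summits (0.606%) than in control windows (1.19%; adjusted exact McNemar p = 0.0143), a call that ended in the strongest 1980 peaks (0.542-fold, adjusted exact p = 0.165). Among the 20 strongest peaks only those in Dhc64C, at Pglym78 and in kirre had a site, each CCAAGGTCG.

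**Figure D3:**
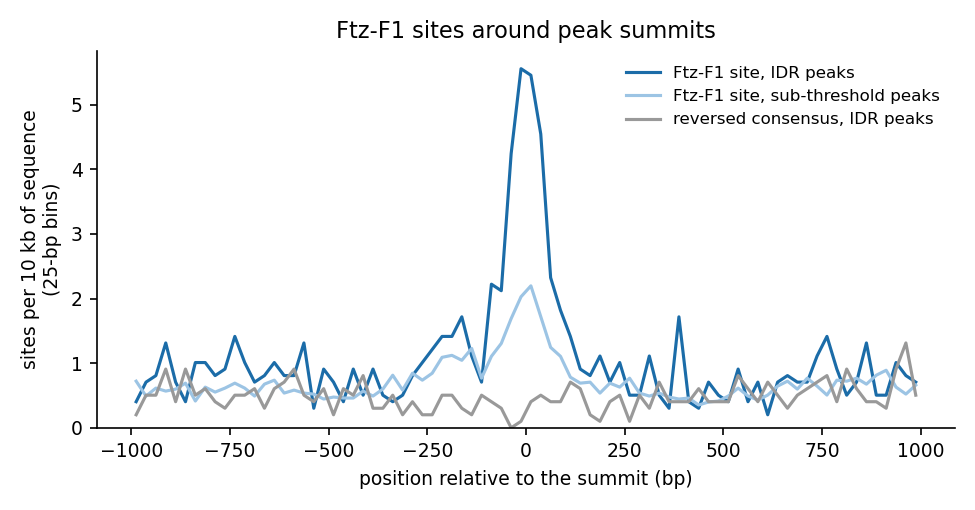
Density of YCAAGGYCR sites, per 10 kb of sequence in 25-bp bins (y axis), by position relative to the summit (x axis, bp), for IDR peaks, sub-threshold peaks and the reversed consensus in IDR peaks. The density in IDR peaks reaches 5.56 beside the summit, and that in sub-threshold peaks reaches 2.20.

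Stronger peaks had the site more often. The 990 IDR peaks with the highest signal values had it in 92 cases (9.29%) and the 990 with the lowest in 50 cases (5.05%; odds ratio 1.93, two-sided Fisher's exact p = 0.000327). Along the pooled list the share was 14% in ranks 1 to 100 (8.53 to 22.1), 5.05% in ranks 2001 to 3960 and 2.51% in ranks 15001 to 29999. Within the IDR list the share in control windows was also higher at the top, 2% in ranks 1 to 100 against 1.07% in ranks 2001 to 3960. The fold over control windows was 4.42 in the strongest 1980 IDR peaks and 4.54 in the whole list. Part of the rise with signal may therefore lie in the surrounding sequence. Sub-threshold peaks as a whole had the site in 2.96% of cases (odds ratio 2.29 for IDR peaks, Fisher's exact p = 1e-25). Peaks with a site had a median signal value of 150 and peaks without one 130, a ratio of 1.15 (permutation p = 6e-05). The site was found at 100 of 2415 promoter summits (4.14%) and at 159 of 1545 distal summits (10.3%; odds ratio 0.377, Fisher's exact p = 6.41e-14).

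**Figure D4:**
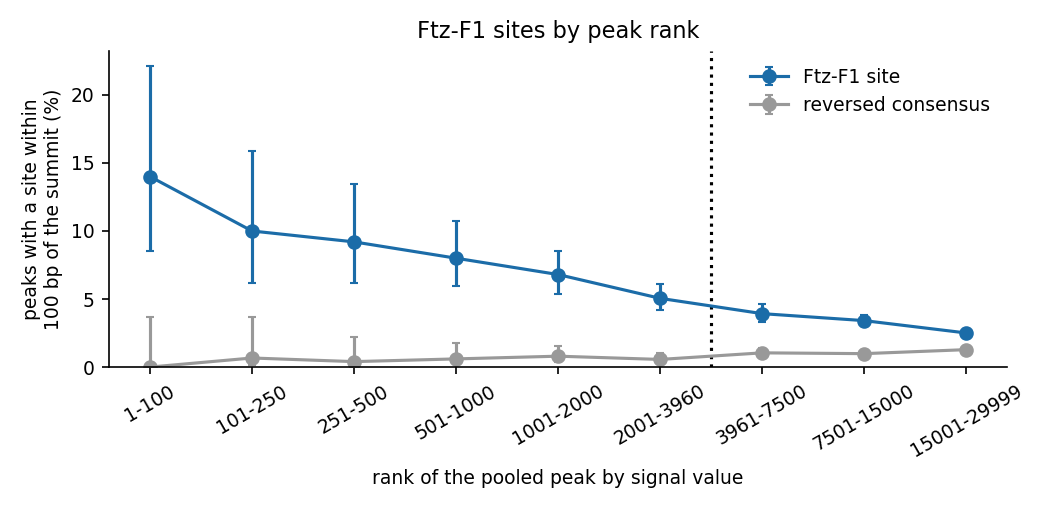
Percent of pooled peaks with a site within 100 bp of the summit (y axis) by rank of signal value (x axis; the dotted line marks the end of the IDR list), for the Ftz-F1 site (blue) and its reversed consensus (grey), with 95% Wilson intervals. The share with the Ftz-F1 site is 14% in the first class and 2.51% in the last.

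Core promoter elements and GAGA sites were more frequent at summits than in control windows. The core promoter elements GGTCACACT and TATCGATA lay at 136 and 150 summits, and the Ftz-F1 consensus YCAAGGYCR at 259. That consensus pools several sequences, while each core promoter element is a single sequence, so these counts do not rank the sites. As single sequences, TCAAGGTCA, the most frequent version of the Ftz-F1 consensus, lay at 67 summits and the shorter CAAGGTCA at 159. The control windows were not matched for promoter position or base composition, and 61.0% of summits lay at promoters. The differences below may therefore reflect where the peaks lie and need not be particular to Ftz-F1. GGTCACACT, the element bound by the promoter factor M1BP, lay at 136 summits (3.43% against 0.177% of control windows, 19.4-fold, adjusted exact McNemar p = 1.97e-31 over 15 motifs). With replicate 1 left out, the M1BP fold was 11 (2.78% against 0.253%). TATCGATA, bound by DREF, a regulator of proliferation and housekeeping genes, lay at 150 (3.79% against 0.606%, 6.25-fold, adjusted exact p = 5.39e-23), and GAGAGA, bound by GAGA factor, at 621 (15.7% against 8.69%, 1.81-fold, adjusted exact p = 1.51e-21). The nuclear receptor core AGGTCA, which overlaps the Ftz-F1 site, was found at 11.1% against 5.93%. Homeodomain sites of the type that Fushi tarazu binds (YAATTA) were less frequent at summits than in control windows (17.7% against 25.4%, 0.697-fold, adjusted exact p = 2.12e-16). So were Zelda sites (0.808% against 1.36%, adjusted exact p = 0.0321), a call that ended in the strongest 1980 peaks (0.607-fold, adjusted exact p = 0.203) and with 1 peak per merged region, an alternative chosen after seeing the data (0.627-fold, adjusted exact p = 0.0672). The Hr3-type site, the EcR/Usp-type inverted repeat, the GATA site, the E-box and the Grainyhead site did not pass. DREF sites were less frequent in peaks with a Ftz-F1 site than in those without one (0.772% against 4.00%, odds ratio 0.187, adjusted p = 0.0422, Fisher's exact test). Peaks with a Ftz-F1 site were also less often at promoters (38.6% against 62.6%), so the DREF difference need not concern the Ftz-F1 site.

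Peaks were sparser on the X and on chromosome 4 than on the other arms. The X held 544 IDR peaks, 13.7% of the list for 17.6% of the analysed length (0.781-fold, two-sided exact binomial p = 6.11e-11, adjusted p = 3.66e-10), or 23.1 per Mb. Arms 2L, 2R, 3L and 3R held between 30.3 and 31.6 per Mb. Chromosome 4 held 12 peaks (8.90 per Mb, 0.301-fold, adjusted exact binomial p = 1.22e-06). Sub-threshold peaks were not scarce on the X, which held 18.3% of them (odds ratio 0.711 for IDR against sub-threshold peaks, p = 6.79e-13, Fisher's exact test). On chromosome 4 they were sparse as well, at 0.549% of sub-threshold peaks for 1.01% of the length, or 106 per Mb against 187 to 202 on the other arms.

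Which gene groups held Ftz-F1 peaks was asked with lists fixed in advance. Of 13945 protein-coding genes, 3634 (26.1%) held an IDR summit in the body or up to 2000 bp upstream. Ribosomal protein genes held peaks far more often than genes of the same length, and odorant and gustatory receptor genes far less often. Of 92 ribosomal protein genes, 53 held a peak, against 16.9 in random lists (3.14-fold, two-sided permutation p = 0.0002, adjusted p = 0.0015, from the smallest p the random lists allow). Their strongest peaks were promoter peaks at RpS28a (3R 30022776, signal value 500.2), RpL7 (2L 10201032, 446), RpL34b (3R 9401302, 391) and RpL19 (2R 24969566, 346). The RpS28a summit lay upstream of the gene, 66 bp from a transcript start of another gene. Of 119 odorant and gustatory receptor genes, 5 held a peak against 25.4 in random lists (0.197-fold, adjusted permutation p = 0.0015). The highest of these were Or88a (3R 14108603, 785, the nearest start being that of CG12402), Gr59e (334), Or9a (123) and Gr64a (96.4). The Gr59e, Or9a and Gr64a summits also lay upstream of the gene, 151, 37 and 52 bp from transcript starts of other genes.

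Of 27 ecdysone response genes, 15 held a peak against 9.34 in random lists. This list did not pass the adjusted threshold (1.61-fold, permutation p = 0.032, adjusted p = 0.16). It passed with the strongest 1980 IDR peaks (2.31-fold, adjusted permutation p = 0.01) and without length matching (2.12-fold, adjusted p = 0.007), a setting in which 66% of simulated length-biased lists passed the unadjusted threshold with no effect. The length bias of that simulation was not fitted to the data. The ecdysone response list did not pass with summits within 500 bp of a start (1.14-fold, adjusted permutation p = 1), by nearest start (adjusted p = 0.279), or with replicate 1 (0.265) or replicate 4 (0.059) left out. Its strongest members were ftz-f1, Hr39 and Eip75B, described above, and Eip74EF (intron, 3L 17614068, signal value 576, ranks 52 and 84 in replicates 1 and 4). Of 15 ecdysteroid synthesis genes 3 held a peak, against 4.82 at random (adjusted permutation p = 1): vvl, which encodes a POU-domain factor (207), mld (123) and ecd (120).

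No list of segmentation genes passed the test against random lists. The random ranges were wide (0 to 5 for the pair-rule genes), and summits beyond the gene and 2000 bp upstream were not counted. By nearest start, 4 of 9 pair-rule genes held a peak against 1.88 (2.13-fold, adjusted permutation p = 0.544). With that rule the fold was 1.52 for segment polarity, 0.758 for gap and head and 0.942 for Hox genes, none passing. The gene ftz (FBgn0001077, 3R, 6864324 to 6866244) had no IDR peak. Its best pooled peak ranked 19017, with a signal value of 28.8. Of the 9 pair-rule genes 3 held a peak against 2.58 at random (adjusted permutation p = 1), namely hry (163), opa (133) and odd (98). The segment polarity gene en (FBgn0000577) had 1 promoter peak at 2R 11528207, with a signal value of 240.2 and ranks of 964 and 357 in replicates 1 and 4. It was 1 of 8 of 16 segment polarity genes with a peak (6.44 at random, adjusted permutation p = 1), beside the Wnt pathway antagonist nkd (intron, 351), the Wnt ligand wg (140) and the Hedgehog receptor ptc (135). Of 15 gap and head genes 3 held a peak (5.10 at random, adjusted permutation p = 0.998), namely cnc (138), nub (127) and noc (101.4). Of 8 Hox genes 2 did, Dfd with a promoter peak (299) and Antp (135), against 3.71 at random (adjusted permutation p = 0.998). The Antp summit lay upstream of the gene in a non-coding exon, 524 bp from a transcript start of another gene. Of 17 dorsoventral patterning genes 7 held a peak against 6.09 (adjusted permutation p = 1), led by ush, Doc3 (229), the mesoderm factor twi (226) and tup (134).

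Lists of tissue markers, included because whole embryos hold every tissue, did not pass either. Of 23 muscle genes 9 held a peak against 9.03 at random (adjusted permutation p = 1). The strongest summits of 3 of these 9, kirre, the integrin gene if (464) and the myogenic factor Mef2 (329), had a Ftz-F1 site within 100 bp, and those of the other muscle genes, Msp300 (190.1) among them, had none. Of 23 neural genes 4 held a peak against 8.61 (0.464-fold, permutation p = 0.0568, adjusted p = 0.213): elav (226), insc (175), Syt1 (122) and nSyb (110.1). The nSyb summit lay upstream of the gene, 164 bp from a transcript start of another gene. With summits within 500 bp of a start the neural fold was 0.172 (permutation p = 0.0186, adjusted p = 0.093). By nearest start it was 0.287 (permutation p = 0.0244, adjusted p = 0.122), and without length matching it was 0.669. Of 15 tracheal genes 5 held a peak against 6.05, led by the FGF ligand bnl (213), vvl, sty (181, with the site CCAAGGTCA) and Mmp1 (143). Of 14 gut and Malpighian tubule genes 5 did against 5.19, among them srp (317), fkh (228), bin (158) and Hnf4 (119, with the site TCAAGGTCA). Of 16 fat body and hemocyte genes 7 did against 5.91, led by ush and srp, with 1 peak shared by the collagen genes vkg and Col4a1 (125). Of 29 cuticle and chitin genes 8 did against 8.18, led by knk (143), the chitin synthase gene kkv (127), mmy (111) and Cht2 (108). The kkv summit lay upstream of the gene, 74 bp from a transcript start of another gene. With replicate 4 left out, 3 of these 29 held a peak against 8.33 (0.360-fold, permutation p = 0.0238, adjusted p = 0.0892). In the IDR list itself the adjusted permutation p was 1 for each of the last 4 lists. The random ranges of lists this small are wide, such as 5 to 14 for the muscle genes, so sizeable differences can be missed.

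**Figure D5:**
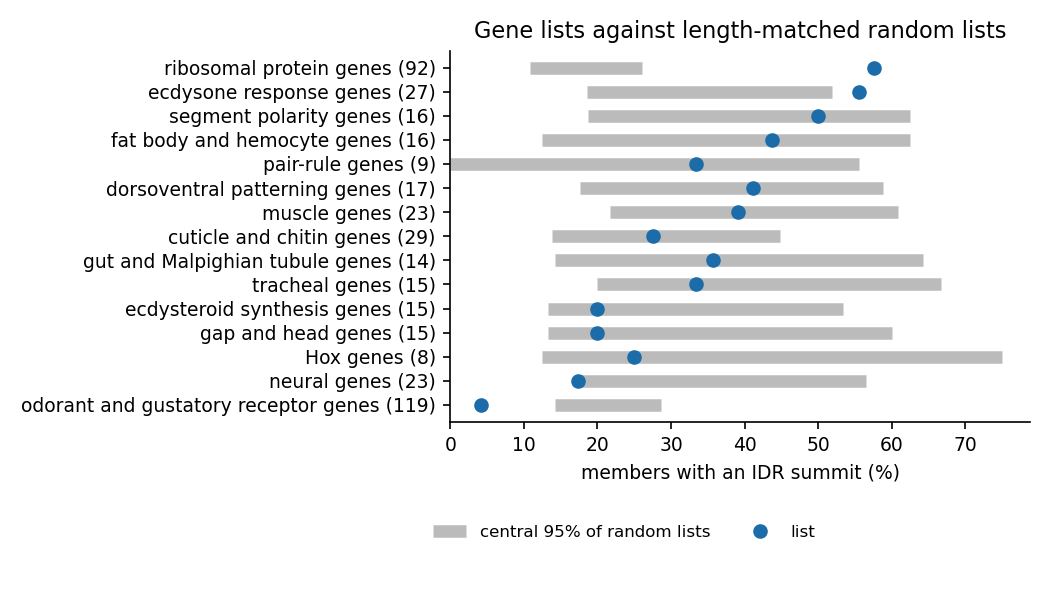
Percent of each list's members (number in brackets) with an IDR summit in the gene body or up to 2000 bp upstream (blue points), with the central 95% of 10000 length-matched random lists (grey bars). Ribosomal protein genes (57.6%) lie above the random range and odorant and gustatory receptor genes (4.202%) below it; ecdysone response genes (55.6%) lie just above theirs but do not pass after adjustment.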

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

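The tests of the 3 patterns below were chosen after the results were seen, except the joining of Eip75B summits, whose outcome was not yet known. The rescaling of X signals was also chosen beforehand, but the criterion for reading it was tightened after its result was seen. In the dm3 lists, peaks outside the 6 chromosome arms were flagged because they numbered more than 3. There were 31 in the pooled list, 41 in the list of replicate 1 and 24 in that of replicate 4. Of these, 22, 31 and 12 lay on heterochromatin scaffolds and the rest on unplaced or mitochondrial sequence. No comparison used these peaks.

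Most IDR peaks, the strongest included, had no Ftz-F1 site. Strictness in the letters before AAGGYCR is argued against as the whole cause, since AAGGYCR alone exceeded its control window by only 11.3 percentage points. Sites that depart from AAGGYCR itself were not sought, so too strict a consensus stays open. False calls near the threshold are argued against as the whole cause, because even among the 100 strongest peaks the upper 95% limit of the share with a site was 22.1%. A partial role of such calls stays open. The share was 5.05% in ranks 2001 to 3960 and 3.93% just below the list, in ranks 3961 to 7500. Enrichment of open promoters without the site is argued against as the whole cause, since among the 1545 peaks away from promoters the share with a site was 10.3%, with an upper 95% limit of 11.9%, and 26.1% with AAGGYCR. A partial role of open promoters stays open, and so does enrichment of open chromatin away from promoters, which was not tested. Background of the tag immunoprecipitation and recruitment of Ftz-F1 by other proteins stay open too. No untagged library was analysed here, and no biological explanation was tested.

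The X held fewer IDR peaks than its length predicts. Fewer callable positions on the X are argued against, since its share of sub-threshold peaks, 18.3%, was above its share of the length, 17.6%. Fewer genes on the X stay open: the upper 95% limit of its share of IDR peaks, 14.8%, was below its share of protein-coding genes, 15.7%, but with replicate 1 left out the limit was 15.9%. A lower X dose in embryos of mixed sex stays open too: multiplying X signals by 4/3 can only raise the X share of the strongest 3960 pooled peaks, and it took it to 21.1% (19.9 to 22.4), past the share of the length, while the X had the most sub-threshold peaks per Mb of any arm (202). The factor assumes equal numbers of male and female embryos and a signal not yet corrected by the control, and no biological explanation was tested.

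IDR summits clustered at Eip75B and ftz-f1, genes that nuclear receptors are known to regulate. At Eip75B, 1 broad region split into many summits is argued against, because 31 regions remained after joining summits less than 1000 bp apart. Extra copies of the ftz-f1 locus in the tagged line are argued against for Eip75B, which lies 686 kb away. For the 22 summits of ftz-f1 itself, extra copies from the transgene and binding to the locus cannot be told apart, because no input library of the tagged line was analysed here. For Eip75B a biological cluster remains a hypothesis, since open chromatin along the gene was not tested.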

How the results depend on the processing

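Of 242 values under alternative settings, 209 kept their direction and their side of the threshold, or stayed within the limit set for counts. These include all alternatives of the replicate overlap (58.6% to 70.5%), promoter share, Ftz-F1 site share (2.29 to 8.37 over windows, definitions and backgrounds, as folds or an odds ratio), its relation to signal (odds ratio 1.76 to 2.89) and to promoters (0.297 to 0.474), the X share (0.708 to 0.839) and the ribosomal protein and receptor lists. The alternative of 1 peak per merged region was chosen after seeing the data. The cause was not tested for any change below, except that the strongest part of the IDR list holds 1980 peaks by construction. Of the changes, 22 are folds that crossed 1 and passed in neither setting. With the control window 2000 bp away, GATA (1.01) and E-box (1.02) folds reversed and the Grainyhead site passed (1.74). With those 1980 peaks the GATA fold reversed (1.02), the reversed Ftz-F1 consensus (0.542) and Zelda (0.607) no longer passed, and Zelda (0.627) did not with 1 peak per merged region. Leaving out each replicate gave 0.884 to 0.940 for the E-box and 1.51 to 1.62 for the Grainyhead site, both passing without replicate 1. The M1BP fold fell from 19.4 to 11 without replicate 1, and that of CAAGGTCA from 8.37 to 5.34 without replicate 4 and 4.42 with the control window 2000 bp away, all still passing. The ecdysone response list passed without length matching (2.12) and with 1980 peaks (2.31), which raised the number of lists above random from 1 to 2 in both. Reversed list folds, none passing, were 0.978 for fat body and hemocyte genes with summits within 500 bp of a start; by nearest start, 1.09 for ecdysteroid synthesis, 1.31 for cuticle, 1.01 for tracheal, 1.37 for muscle and 1.44 for gut genes; without length matching, 1.06 for cuticle, 1.29 for tracheal, 1.501 for muscle and 1.36 for gut genes; and with 1980 peaks, 1.09 for tracheal, 1.09 for muscle and 0.560 for fat body and hemocyte genes. Leaving out each replicate gave 0.758 to 1.203 for pair-rule, 0.815 to 1.33 for dorsoventral, 0.360 to 1.13 for cuticle, 0.993 to 1.17 for tracheal and 0.843 to 0.860 for fat body and hemocyte genes. Depth is unknown, so which weak sites went unlisted is unknown too.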

Other observations

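The tests in this part were chosen after the main results were seen; the outcomes of the homeodomain, nuclear receptor and ribosomal protein tests were not yet known. Among peaks with a Ftz-F1 site, the strongest after Dhc64C, Pglym78 and kirre were at the promoters of CG3420 (2R 6757265, signal value 819) and CG12402 (3R 14108603, 785). Eip75B followed with 3 of the next peaks, in introns at 3L 17995335 (738, TCAAGGTCG) and 18022761 (596, CCAAGGCCA) and beyond the gene's end at 17950561 (639, TCAAGGTCA). Others lay in an intron of PyK, the pyruvate kinase gene (3R 22368489, 638, TCAAGGTCA), and at the promoter of fz, a Wnt receptor gene (3L 14274181, 581, TCAAGGTCG). Within Eip75B, 8 of 42 summits (19.0%) had a site, an odds ratio of 3.44 against all other IDR peaks (Fisher's exact p = 0.00505, adjusted p = 0.0556 over 11 genes). In ftz-f1 it was 1 of 22, and in Eip74EF 0 of 15. Of 6878 sites on the 6 arms, 281 (4.09%) had their centre within 100 bp of an IDR summit, a wider rule than the whole site within 100 bp used for peaks.

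Several developmental regulators without an IDR peak had no pooled peak in the gene or up to 2000 bp upstream, among them run, slp1, slp2, hb, gt, tll and hkb. Others had best pooled ranks from just below the end of the IDR list, such as 4052 for hh, 4288 for btd, 4456 for ems, 4919 for lab and 5122 for Ubx, to 12822 for eve, 15840 for prd and 23779 for Kr.

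One hypothesis was that Ftz-F1 sites in IDR peaks lie close to homeodomain sites, as joint binding with Fushi tarazu would predict. Neither comparison showed such an excess. A YAATTA site lay within 50 bp of 19 of those 281 Ftz-F1 sites (6.76%) and of 462 of 4195 sites over 1000 bp from any pooled summit (11.01%; odds ratio 0.586, Fisher's exact p = 0.028). YAATTA is also less frequent at IDR summits in general, so that difference need not concern the Ftz-F1 site. Within the IDR list, YAATTA lay within 100 bp of 16.6% of summits with a Ftz-F1 site and 17.8% of those without (odds ratio 0.921, Fisher's exact p = 0.674). Embryos of 0 to 24 hours are mostly past the stage of pair-rule expression, so an early association in few embryos could be missed by the odds ratio of 0.586.

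A further hypothesis was that nuclear receptor genes as a family hold IDR peaks more often than other genes of their length. Of 21 such genes 13 did against 8.29 at random (1.57-fold, two-sided permutation p = 0.0604), which leaves it open. Those with a peak were EcR, Eip75B, Eip78C, Hr3, Hr4, Hr38, Hr39, Hr78, Hr96, ERR, Hnf4, svp and ftz-f1. Many are also in the ecdysone response list, so the result is not independent of it.

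Ribosomal protein genes were also compared with other genes that had any pooled peak within 500 bp of a transcript start, to ask whether promoters open to calling account for the excess. Of 83 such ribosomal protein genes, 46 (55.4%) had an IDR summit there, against 2526 of 7972 other genes (31.7%; odds ratio 2.68, Fisher's exact p = 1.35e-05). The IDR list is the strongest part of the pooled list, so this excess only restates a higher signal at these promoters. Highly transcribed promoters are a possible explanation that peak lists cannot test. Of 119 odorant and gustatory receptor genes, 4 had any pooled summit at a promoter, and 1 of those an IDR summit.

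The peaks that only 1 replicate ranked highly differed between the replicates. Among the strongest 3960 peaks, the 1212 found only in replicate 1 had a mean GC content of 40.9% ± 6.84 (SD over peaks) within 100 bp of the summit. The 1152 found only in replicate 4 had 50.03% ± 7.55 (permutation p = 1e-05, the smallest the permutations can give). The X held 141 of the former (11.6%) and 226 of the latter (19.6%; odds ratio 1.85, Fisher's exact p = 8.38e-08). Ftz-F1 sites were found in 4.46% and 4.86% of them, against 7.06% and 7.12% of the shared peaks of replicates 1 and 4.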
